A study of Mus musculus with 4 samples.

How the data were processed

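Foxp3-positive CD4 T cells from mouse spleen were profiled by droplet sequencing of RNA, of surface protein antibodies (ICOS, GITR, PD-1, CD25 and CD44 among them) and of 3 hashtag antibodies, in 4 pools of 3 mice, 12 mice in all. Per the labels, each pool holds a mouse given an IL-2 mutein, a mouse given wild-type IL-2 and a mouse given PBS. The deposited matrices hold raw UMI counts per feature and barcode, with 32285 genes. They were made with Cell Ranger 6.1.1 against mm10, per the submitters' processing notes, and filters beyond the deposited barcode list are not stated. The hashtags carry the names HTO_M1, HTO_M2 and HTO_M3 in each pool. Neither the labels nor the feature lists say which hashtag marks which treatment, or that a hashtag marks the same treatment in each pool. The planned comparisons of treatments were therefore made between hashtags by name, and no treatment was assigned. If hashtags were shuffled over treatments between pools, a hashtag would mix treatments. Median UMIs per cell ran from 3741 to 4139 in HTO_M1, 4902 to 5406 in HTO_M2 and 8261 to 9856 in HTO_M3, in the same order in each pool. If treatment sets these values, this argues against shuffling, but whether it does was not tested.

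The pools held 11931, 14041, 13027 and 12235 barcodes (51234 in all), with medians of 5897, 5585, 5713 and 5804 gene UMIs per barcode and a smallest total of 500. Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept (11848, 13927, 12930 and 12067). Hashtags were called with HTODemux in Seurat 5.3.0 at a quantile of 0.99. This removed 1964, 2410, 1714 and 1001 doublets and 126, 305, 123 and 558 barcodes without a hashtag, and left 9758, 11212, 11093 and 10508 cells, 42571 in all or 83.1% of barcodes. A rule that takes the top hashtag at 10 or more UMIs and at least 3 times the next gave the same hashtag to 99.4% to 99.9% of these cells in each pool. Scrublet called 0 cells in each pool and has not worked here, so keeping the cells it calls would change nothing and was not run. Doublets within a mouse remain. As an added alternative, the 982, 1205, 857 and 500 cells with most hashtag doublets among their 30 nearest neighbours were left out.

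Cells were normalised to 10000 UMIs, log-transformed and clustered in scanpy 1.11.5 on 2000 variable genes, 30 principal components, 15 neighbours and a shared-neighbour graph, with leidenalg 0.10.2 at a resolution of 0.5 (alternative 1.0). The genes of 7 outcome lists, mitochondrial and ribosomal genes, T cell receptor segments and Xist were left out of the clustering. A cluster was named when at least 3 markers of a list were among its top 50 genes, no other list had more markers in the top 10, and its UMIs per cell were at least 0.5 of the pool median. That rule was set after the clusters were seen. Names end in -like because they rest on marker genes alone. Another clustering left out 2223 genes that differ between hashtags.

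UMI counts were summed per pool and hashtag, or per pool and class, and tested in edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood fit and test) in R 4.3.3, with pool as block and a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM beside a fold change are scaled by TMM factors, and the CPM of Il10 by mouse are plain. Libraries of a pool share a capture. Deviations from group means correlated across genes within pools by 0.187 on average between hashtags (lowest 0.0258), by 0.253 between effector-like and resting-like cells, by 0.192 between cycling-like and other cells and by 0.0953 between Il10-positive and Il10-negative cells. Within effector-like and follicular-like cells the lowest value was below 0 (-0.00484 and -0.0142), and the block was kept since the labels give each pool as a unit. No pair of libraries was identical. Cells with at least 1 Il10 UMI were compared with as many effector-like cells without, drawn from the same pool and decile of total UMIs, leaving Il10 out of the test. In the comparisons of classes only outcome genes are results.

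Lists were tested with camera (limma 3.58.1, preset correlation of 0.01), again with an estimated correlation and with fry, adjusted over the lists of a comparison. The outcome lists are suppression, IL-2 and STAT5 response, homing, transcription factors, costimulation, glycolysis and cholesterol synthesis. The marker lists are resting, effector, cycling, interferon, follicular, immediate early, conventional CD4, gamma-delta T, NK, B, plasma and myeloid cells. Lists of CD8 T, dendritic, erythroid, platelet and stromal cells had too few tested members, as had conventional CD4, gamma-delta T, NK, plasma and myeloid cells in the Il10 comparison. List tests within classes were run and are not reported. Shares, protein values and UMIs per cell were compared between hashtags by two-sided exact permutation tests of 4 against 4 mice, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment within each family. Within-pool sign flips cannot go below 0.125. Protein values are mean antibody UMIs per cell on the log2 scale. Intervals of shares are exact (Clopper-Pearson, 95%) and cover counting error only.

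Genes named were chosen by a rule: Il10, Ctla4, Foxp3, Il2ra and Il2rb in every case; from each outcome list the 2 highest and 2 lowest called members; and the 8 largest changes each way among called genes at 20 CPM or more that moved the same way in 4 pools and are not cell type markers, ribosomal, mitochondrial, numbered or receptor segment genes. Mki67, Maf, single members of marker lists and the genes of cluster descriptions were named for other reasons after their values were seen. A fold against 1 to 3 counts is given as a ratio with its counting interval, and one against 0 counts as a bound from a floor of 3 counts over the group. Some genes that the rule names, and a surface protein that was tested in the same family of 18 tests, are not reported here. Coordinates are from GENCODE vM21 on mm10 (32158 genes with coordinates, 127 without). Reads shared between Ifitm1, Ifitm2 and Ifitm3, or between Gzma and Gzmb, cannot be excluded.

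The tests, gene lists, alternatives and gene rule were chosen before the data were examined. Comparisons within classes, of proteins, with mouse as block, within HTO_M3 and with library size only were added after. Alternatives were DESeq2 1.42.0, RLE factors, no count filter, no block, leaving out each pool, a stricter cell filter (1000 genes, 5%), the hashtag rule, another resolution, outcome genes kept, thinned cells, no depth matching and at least 2 Il10 UMIs. The fits were tested on a single simulated draw per comparison, without pool effects, with 200 changed genes at 1.5-fold and 2-fold. Most real comparisons called far more genes, so the rates below need not hold for them. For the libraries of the hashtag comparison, edgeR found 70% and 85% of these, with 7.19% of calls false. It found 77% and 95% (4.97% false) for effector-like against resting-like cells, 80% and 92% (4.97%) for cycling-like cells and 32% and 80% (6.67%) for the Il10 comparison, so false calls exceeded 5% of calls in 2 of these. The same for DESeq2 were 67% and 81% (8.07%), 69% and 87% (0.637%), 76% and 87% (6.32%) and 15% and 40% (0%). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.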

Results

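Regulatory T cells from mouse spleen (CD4 T cells that carry the transcription factor Foxp3 and restrain other immune cells) were profiled in 4 pools of 3 mice by droplet RNA sequencing with antibody tags. Per the labels, every pool mixes a mouse given an IL-2 mutein (an engineered form of the T cell growth factor IL-2), a mouse given wild-type IL-2 and a mouse given PBS. No label ties a hashtag antibody to a treatment, so mice were compared by hashtag (HTO_M1, HTO_M2, HTO_M3) and no hashtag was assigned a treatment. Pools 1 to 4 held 97746809, 109066012, 93953208 and 92188228 gene UMIs. After filtering, 42571 cells carried a single hashtag: 13849 HTO_M1, 13928 HTO_M2 and 14794 HTO_M3 cells, from 4 mice per hashtag. Values after ± are SDs over mice or pools, SE is the standard error of a fit, and n = 4 throughout unless stated.

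Positions are on mouse build mm10. Il10 (ENSMUSG00000016529) lies on chromosome 1 from 131019845 to 131024974, Ctla4 (ENSMUSG00000026011) on chromosome 1 from 60887000 to 60915832, and Foxp3 (ENSMUSG00000039521) on chromosome X from 7573644 to 7595245. Il2ra (ENSMUSG00000026770) lies on chromosome 2 from 11642807 to 11693193, and Il2rb (ENSMUSG00000068227) on chromosome 15 from 78479256 to 78495271. Gzmb lies on chromosome 14 from 56258838 to 56262260, Ifitm1 on chromosome 7 from 140967221 to 140969825, Socs2 on chromosome 10 from 95385362 to 95417180, Lag3 on chromosome 6 from 124904361 to 124911705, and Tigit on chromosome 16 from 43648867 to 43664146.

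Clusters were named from marker genes. Resting-like cells (15277) were marked by Ccr7, a receptor that guides T cells into lymphoid tissue, with Dapl1 and Satb1. Effector-like cells (7996) were marked by S100a4, S100a6 and Lgals3, by the inhibitory receptor Klrg1, the integrin Itgae, the costimulatory receptor Icos and the transcription factor Maf. Follicular-like cells (6718) were marked by Bcl6, Pdcd1, Tox2, Sostdc1 and Il1r2, genes of the regulatory cells that enter B cell follicles. Penk, Ccl5, Rgs16, Egr2, Nr4a1 and Egr1 were also among the top genes of this cluster, so it may hold other cells as well. Cycling-like cells (2934 and 2357 in a pair of clusters) were marked by Ccnb2, Mcm5, Birc5, Cdk1 and Pclaf, and interferon-like cells (1014) by Ifit1, Ifit3, Isg15 and Rsad2. A cluster of 5303 cells with high Tcrg-C1, Plac8 and Igfbp4 stayed unnamed (cluster 3). Its best list was that of resting markers, with 2 (Dapl1 and Igfbp4) among its top 50 genes, under the 3 that a name needs. Another cluster, of 972 cells with a median of 2215 UMIs, of which 669 came from pool 2, also stayed unnamed (cluster 7). Its best list was that of cycling markers, with 2 (Cenpe and Mki67) among its top 50 genes. Of its cells, 565 were HTO_M3 cells and 32.0% had an Mki67 UMI, at a median of 4.39% mitochondrial UMIs. These cells are not counted as cycling-like.

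Over the 4 pools, each a mixture of 3 hashtags, resting-like cells made up 35.8% ± 2.30 of cells, effector-like cells 18.8% ± 1.54, follicular-like cells 15.9% ± 2.72, cycling-like cells 12.5% ± 2.76 and interferon-like cells 2.37% ± 0.430. Cluster 3 held 12.5% ± 1.34 and cluster 7 held 2.23% ± 2.53. In pool 1, 3185 of 9758 cells were resting-like, with an exact 95% binomial interval of 31.7% to 33.6%, and 193 were interferon-like (1.71% to 2.27%), an interval that is not small beside the spread over pools.

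Resting-like cells fell from 63.2% ± 2.71 of HTO_M1 cells to 39.6% ± 2.35 of HTO_M2 cells and 6.47% ± 4.77 of HTO_M3 cells. Unnamed cluster 3, whose best list was that of resting markers, held 30.4% of HTO_M3 and 0.575% of HTO_M1 cells and is not counted as resting-like. The size of this fall therefore depends on the naming rule. Effector-like cells rose from 6.85% ± 2.03 in HTO_M1 to 33.2% ± 1.31 in HTO_M2, and stood at 16.3% ± 3.37 in HTO_M3. Cycling-like cells made up 34.3% ± 8.06 of HTO_M3 cells, against 0.478% ± 0.493 in HTO_M1 and 1.30% ± 0.256 in HTO_M2. Follicular-like cells fell from 25.5% ± 3.39 in HTO_M1 to 6.26% ± 1.30 in HTO_M3, with 16.7% ± 4.65 in HTO_M2. Shares are relative, so the large cycling-like class and cluster 3 of HTO_M3 lower the shares of its other classes. A lower share need not mean fewer cells in the spleen, since these counts give no absolute cell numbers. For resting-like and effector-like cells in all 3 contrasts, and for follicular-like and cycling-like cells in the contrasts with HTO_M3, the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 mice allow (Benjamini-Hochberg adjusted p = 0.0429 over 15 tests), with the same direction in 4 of 4 pools. Follicular-like and cycling-like cells did not pass between HTO_M2 and HTO_M1 (exact p = 0.0571, adjusted p = 0.0714, a test that ignores the pool), although each moved in the same direction in 4 of 4 pools, nor did interferon-like cells in any contrast (2.22% ± 1.26, 2.45% ± 0.725 and 2.40% ± 1.14, exact p from 0.771 to 0.971). Leaving out any pool leaves 3 against 3 mice, whose smallest exact p is 0.1. The shares depend on the clustering. At a Leiden resolution of 1.0 resting-like cells made up 11.8%, 10.9% and 2.16% of HTO_M1, HTO_M2 and HTO_M3 cells, effector-like cells 4.36%, 20.8% and 12.8%, and follicular-like cells 18.0%, 12.6% and 4.35%. The resting-like share stayed lower in HTO_M3 (exact p = 0.0286 against each of the others), by several-fold fewer percentage points. The resting-like contrast of HTO_M2 with HTO_M1 gave an exact p of 0.714 there. At this resolution clusters 0, 2, 4, 5 and 13 stayed unnamed. The resting-like class held 8.15% of cells over pools, against 35.8% at 0.5, so that contrast compares a smaller set of cells. Cluster 8 was named immediate-early-like there, a name that no cluster had at 0.5. The follicular-like class held 11.5% of cells over pools, against 15.9% at 0.5. Whether the cells of cluster 8 came from it was not tested. With the outcome genes kept in the clustering the effector-like contrast of HTO_M3 with HTO_M1 gave an exact p of 0.0571, at 10.3% and 6.52% of cells.

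Hashtags differ in expression and clusters were drawn from expression, so shares were also taken from a clustering without the 2223 genes that differed most between hashtags. Many genes with smaller differences remain in it. There resting-like cells made up 64.4%, 36.5% and 6.89% of HTO_M1, HTO_M2 and HTO_M3 cells, effector-like cells 6.80%, 32.6% and 18.3%, follicular-like cells 24.1%, 18.7% and 7.56%, cycling-like cells 0.360%, 0.657% and 25.9%, and interferon-like cells 1.68%, 2.43% and 4.53%. In the clustering that kept those 2223 genes, unnamed cluster 3 held 0.575% ± 0.0624, 5.12% ± 0.627 and 30.4% ± 2.74 of HTO_M1, HTO_M2 and HTO_M3 cells (exact p = 0.0286, adjusted p = 0.0571, each contrast), and cluster 7 held 1.17%, 1.61% and 3.90%. Median UMIs per cell were 3932 ± 163, 5132 ± 222 and 9320 ± 718 for HTO_M1, HTO_M2 and HTO_M3 (exact p = 0.0286, adjusted p = 0.0490, each contrast). The median mitochondrial share of UMIs was 1.72% ± 0.0823, 1.52% ± 0.0873 and 1.43% ± 0.1, lower in HTO_M3 than in HTO_M1 in 4 of 4 pools (exact p = 0.0286, adjusted p = 0.0490) and not passing in the other contrasts (exact p = 0.0571 and 0.257).

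**Figure D1:**
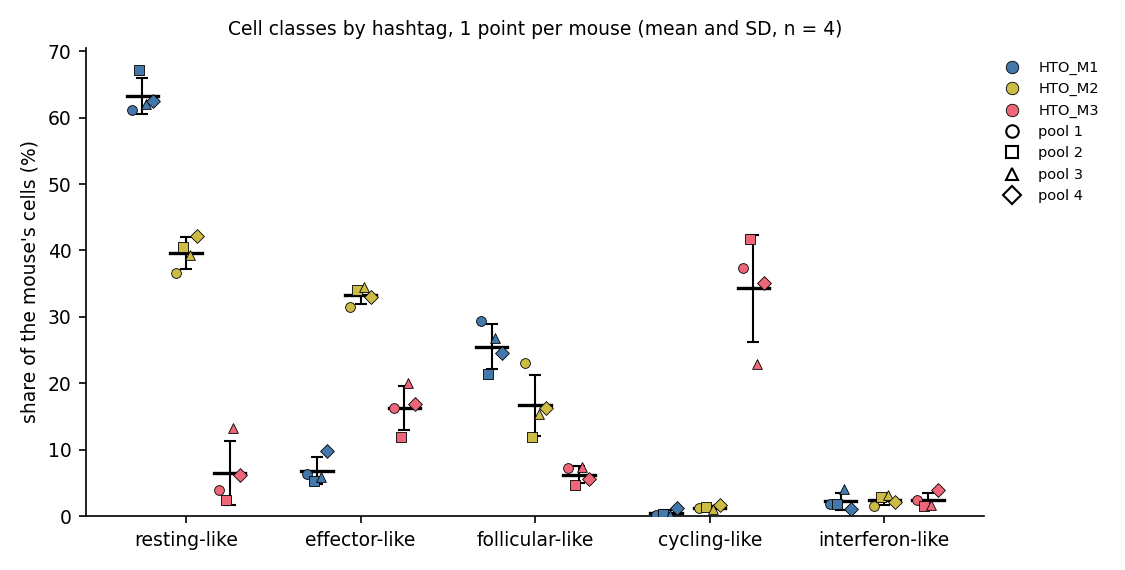
Share of each mouse's cells (%) in the 5 named classes, by hashtag; each point is a mouse, its shape the pool, and bars give the mean and SD over 4 mice. Resting-like cells average 63.2% in HTO_M1 and 6.47% in HTO_M3, and cycling-like cells 0.478% and 34.3%.

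Cells with at least 1 UMI of Mki67, a gene of dividing cells, were counted after thinning every cell to 2000 UMIs, because HTO_M3 cells are deeper. Their share was 1.15% ± 0.376 in HTO_M1, 3.14% ± 0.686 in HTO_M2 and 17.8% ± 5.23 in HTO_M3 (exact p = 0.0286 for each of the 3 contrasts, adjusted p = 0.0286, 4 of 4 pools). Thinning left out 737, 503 and 241 cells with fewer UMIs. Without thinning, 1.96% of resting-like cells carried an Mki67 UMI at a median of 4354 UMIs, against 80.8% of cycling-like cells at 14546. The shares by hashtag were then 2.40% ± 1.06, 7.81% ± 1.08 and 35.5% ± 7.83, and 8775 of the 15277 resting-like cells were HTO_M1 cells. Leaving out any pool leaves 3 against 3 mice and an exact p of 0.1.

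Genes and lists were first compared between hashtags on counts summed over all cells. These sums mix changes within classes with the changed shares of the classes, and do not tell the 2 apart. Changes of genes and lists, here and within classes, are relative to total UMIs. Where cells differ in total UMIs, a fall need not be a fall per cell. Single genes were compared in UMIs per cell for Il10 alone, in HTO_M3 and HTO_M1. Between HTO_M2 and HTO_M1 cells, Gzmb, a cytotoxic granule protease, rose by 2.57 on the log2 scale in HTO_M2 (SE 0.28, adjusted p = 2.3e-05, edgeR), from 8.20 ± 4.68 to 48.3 ± 20.3 CPM. Ccr2, a chemokine receptor for entry into inflamed tissue, rose by 2.41 (SE 0.20), and the granule protease Gzma by 2.11 (SE 0.44). Myc, a growth regulator induced by IL-2, fell by 0.94 (SE 0.07), and the cytokine gene Lta, also induced by IL-2, fell by 1.01 (SE 0.10). Il2ra, the alpha chain of the IL-2 receptor (CD25), fell by 0.25 (SE 0.05, adjusted p = 0.0019, edgeR), from 251 ± 20.9 to 210.3 ± 12.8 CPM.

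Of 12120 genes tested between HTO_M2 and HTO_M1 by edgeR, 4701 changed, 2419 up and 2282 down in HTO_M2 (2728 and 2036 with library size only), and 385 of these by more than 2-fold. Il2rb, the receptor's beta chain, fell by 0.17 (SE 0.05, adjusted p = 0.022, edgeR; not called without pool 4, at negative 0.16), and Ctla4, a suppressive surface receptor, rose by 0.35 (SE 0.06, adjusted p = 0.0011). Foxp3, the lineage's transcription factor, was not called (log2 difference of negative 0.03, SE 0.05), nor was the suppressive cytokine gene Il10 (0.09, SE 0.31; negative 0.12 without pool 2 and negative 0.04 without pool 3). Rises were also of Ifitm3, an interferon-induced membrane gene (1.87), the myosin gene Myo1f (1.86), the annexin Anxa2 (1.81), the G protein Gna15 (1.73), the phosphatase Cdc25b (1.58) and the antiviral gene Oas1a (1.47). Falls were also of Rgs16, a G protein regulator (1.34), the tubulins Tubb2a (1.11) and Tuba1b (0.98), the ribosome maturation gene Mdn1 and the RNA host gene Snhg15 (both 0.90), and the chromatin gene Hmgn1 (0.87). The transcription factors Tbx21 (1.05) and Rora (0.98), the costimulatory ligand Cd80 (1.15) and the IL-2 feedback gene Socs2 (0.67) also rose. Myb (0.70), Cxcr4 (0.58), Ccr8 (0.53) and Cd83 (0.47) fell.

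In the list of homing receptors and adhesion genes, 11 rose between HTO_M1 and HTO_M2 (Ccr2 among them), 3 fell (Cxcr4, Ccr8) and 5 were not called (camera adjusted p = 0.00765, up; adjusted p = 0.209 with an estimated correlation). Of the IL-2 and STAT5 response genes, 3 rose (Socs2, Pim1), 14 fell (Lta, Myc) and 6 were not called (camera adjusted p = 0.00918, down; adjusted p = 0.201 with an estimated correlation). Suppression genes were 7 up (Gzmb, Gzma), 2 down (Prf1, Itgb8) and 8 not called (0.0230, up; 0.201 estimated). Cholesterol synthesis genes were 7 up (Mvk, Hmgcs1) and 12 not called (0.0230, up; 0.519 estimated), and glycolysis genes 6 up (Gpi1, Ldha), 2 down (Pfkl, Eno1) and 7 not called (0.0230, up; 0.422 estimated). Costimulation genes (6 up, 3 down, 10 not called; camera adjusted p = 0.232) and transcription factors (8 up, 8 down, 11 not called; 0.606) did not pass. When adjusted over the list alone, glycolysis had 8 up and 2 down and transcription factors 9 up and 9 down, and the other 5 lists kept their counts. Without pool 1 the genes Eno1 (negative 0.23), Sc5d (0.20) and Prf1 (negative 0.42) were not called. Without pool 2 these were Prf1 (negative 0.42), Pfkl (negative 0.15) and Itgb8 (negative 0.37), without pool 3 Eno1 (negative 0.18), Eomes (negative 0.64) and Prf1 (negative 0.53), and without pool 4 Eno1 (negative 0.23), Sc5d (0.11) and Eomes (negative 0.43). With DESeq2 and without cells near hashtag doublets Eomes (negative 0.59 and negative 0.45) and Prf1 (negative 0.51 and negative 0.44) were not called, nor without the pool block Eomes (negative 0.60) and Eno1 (negative 0.21), nor Eno1 with library size only (negative 0.18) or the ratio rule for hashtags (negative 0.16). The number of lists past 0.05 fell from 5 of 7 to 3 without pool 4.

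HTO_M3 and HTO_M1 cells differed by larger folds. Ifitm1, an interferon-induced membrane gene, rose by 6.79 on the log2 scale in HTO_M3 (SE 0.25, adjusted p = 1.6e-10, edgeR), from 0.774 ± 0.351 to 87.0 ± 14.2 CPM. Gzmb rose by 5.39 (SE 0.28, 41.9-fold), and Gzma by 5.12 (SE 0.31, 34.7-fold). Il2ra rose by 1.10 (SE 0.05, adjusted p = 9.2e-10, edgeR), from 251 ± 20.9 to 541 ± 64.5 CPM, and Il2rb by 0.85 (SE 0.05). Socs2, a feedback inhibitor induced through STAT5, rose by 2.53 (SE 0.09), whereas Eomes, a transcription factor of cytotoxic lymphocytes, fell by 3.77 (SE 0.24).

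Of the 12120 genes, 8597 changed between HTO_M3 and HTO_M1, 4291 up and 4306 down (3846 and 4861 with library size only), 1854 of them by more than 2-fold. Median UMIs per cell were 9320 in HTO_M3 and 3932 in HTO_M1, so the smaller falls below need not be falls per cell. The cell division genes Cdkn3 (5.01), Tpx2 (4.81) and Spc24 (4.75) rose, as did Ifitm3 (4.94), Ifitm2 (4.80) and the galectin Lgals7 (4.82). Ctla4 rose by 0.34 (SE 0.06, adjusted p = 0.00036, edgeR), and Foxp3 was not called (negative 0.01, SE 0.05; 0.01 with DESeq2 and 0.04 without pool 1). Il10 fell by 1.54 (SE 0.33, adjusted p = 0.0010, edgeR) on 128 UMIs in HTO_M3 and 148 in HTO_M1, while per 1000 cells the 4 mice averaged 8.58 ± 3.82 and 10.8 ± 7.16 Il10 UMIs (exact permutation p = 0.714). Further falls were of the cytoskeletal regulator Rhob (2.68), the activation marker Cd83 (2.48), the chemokine Ccl5 (2.31), the sialyltransferase St8sia6 (2.24), the chemokine receptor Ccr6 (2.05), the tubulin Tubb2a (1.95), Jade2 (1.83), Frat2 (1.80), Gsta4 (1.78), Itgb8 (1.6), Ccr8 (1.45), Tnfsf8 (1.25), Klf6 (0.94), Pim2 (0.85) and Stat5b (0.80). The homing receptor Ccr4 (1.67), the cyclin partner Cdk6 (1.22), Cd80 (0.72), Irf4 (0.51) and Tnfrsf18 (0.38) rose. Slc2a3 fell by 0.14 with all pools (adjusted p = 0.033, edgeR) and was not called without pool 1, 2 or 4 (negative 0.16, negative 0.11 and negative 0.14), nor with DESeq2 (negative 0.12), no count filter (negative 0.10) or no pool block (negative 0.14). Id3 (0.23) was not called without the pool block, nor Pfkl (negative 0.17) with DESeq2.

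All but 3 of 19 cholesterol synthesis genes rose in HTO_M3 over HTO_M1 (Mvd by 1.55, Idi1 by 1.42), and none fell (camera adjusted p = 5.2e-05; adjusted p = 0.353 with an estimated correlation). Of glycolysis genes, 11 rose (Ldha by 1.31, Tpi1 by 1.28), 3 fell (Pfkl, Slc2a3) and 1 was not called (0.0152, up; 0.353 estimated). Of transcription factors, 4 rose (Irf4, Id3), 15 fell (Eomes, Klf6) and 8 were not called (0.0414, down; 0.353 estimated). Not passing were costimulation (2 up, 10 down, 7 not called; 0.0601), IL-2 and STAT5 response (14 up, 9 down; 0.433), homing (9 up, 8 down, 2 not called; 0.95) and suppression (8 up, 8 down, 1 not called; 0.95). With p values adjusted over the list alone, the counts were the same in all 7 lists. For homing the test pointed up with a median of negative 0.06 and a mean of 0.05, and for suppression it pointed down with a median of negative 0.01 and a mean of 0.39.

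Between HTO_M3 and HTO_M2, the IL-2 response genes Socs2 and Cish, both feedback inhibitors of cytokine signalling, rose by 1.86 (SE 0.09) and 1.61 (SE 0.06). Il2ra rose by 1.36 (SE 0.05, adjusted p = 2.3e-10, edgeR) and Il2rb by 1.02 (SE 0.05). Il10 fell by 1.64 (SE 0.32, adjusted p = 0.00047, edgeR), and Lag3, an inhibitory receptor, fell by 1.40 (SE 0.14). Il10 had 128 UMIs in 14794 HTO_M3 cells and 209 in 13928 HTO_M2 cells. Median UMIs per cell were 9320 and 5132, and a fall of Il10 per cell was not tested in this contrast. Ctla4 and Foxp3 were not called (negative 0.01 and 0.03). Ctla4 stood at 0.01 with DESeq2 and at 0.02, 0.00 and 0.02 without pools 2, 3 and 4, and Foxp3 at negative 0.06 with library size only. Ifitm1 (5.64), Drc1, a gene of the ciliary axoneme (5.33), and Mxd3, a repressor of the Myc network (4.06), rose.

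In this contrast 8234 of 12120 genes changed, 4001 up and 4233 down in HTO_M3 (3365 and 5086 with library size only), 1442 by more than 2-fold. The division and replication genes Spc24 (4.01), Clspn (3.94) and Asf1b (3.93) rose, with Ifitm2 (3.95), Gzma (3.01), Gzmb (2.81), Mvd (1.31), Idi1 (1.29), Eno1 (1.13), Tpi1 (0.96) and Myb (0.86). Falls were of Eomes (3.17), Ccl5 (2.88), Cd83 (2.01), St8sia6 (1.91), Ccr6 (1.81), the kinase Matk (1.68), Cxcr6 and the ligase Neurl3 (both 1.61), Rora (1.58), Rflnb (1.57), the class II chaperone H2-Ob (1.54), Cd200 (1.00), Stat5b (0.76) and Pim2 (0.54). With library size as the only scaling, the median of all genes moves to negative 0.12 (negative 0.03 with TMM), and changes are stated relative to TMM. Of IL-2 and STAT5 response genes, 17 rose (Socs2, Cish) and 6 fell (Stat5b, Pim2) (camera adjusted p = 0.00694, up; adjusted p = 0.140 with an estimated correlation). Cholesterol synthesis had 17 up (Mvd, Idi1) and 2 not called (2.9e-05, up; 0.293 estimated), and glycolysis 9 up (Eno1, Tpi1), 3 down (Slc2a3, Aldoa) and 3 not called (0.0279, up; 0.301 estimated). Costimulation had 1 up (Tnfrsf18), 14 down (Cd83, Cd200) and 4 not called (0.00221, down; 0.140 estimated), transcription factors 4 up (Myb, Irf8), 18 down (Eomes, Rora) and 5 not called (0.00313, down; 0.140 estimated), and homing 5 up (Ccr4, Itgb7), 10 down (Ccr6, Cxcr6) and 4 not called (0.0479, down; 0.301 estimated). Suppression genes (6 up, 9 down, 2 not called) did not pass (0.321), and adjusted over the list alone had 7 up, with the other 6 lists unchanged. Insig1 rose by 0.19 and was not called without pool 2 (0.14), with library size only (0.11) or without the pool block (0.20).

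The marker lists used for naming were tested between hashtags as well, and no list passed 0.05 with an estimated correlation in any of the 3 contrasts. Cycling markers rose in HTO_M3, 22 of 22 over HTO_M1 and 22 of 22 over HTO_M2 (camera adjusted p = 2.2e-11 and 2.6e-12; adjusted p = 0.365 and 0.463 with an estimated correlation). In HTO_M2 over HTO_M1, 15 rose and 5 fell (0.00723; 0.691 estimated). Effector markers rose in HTO_M2 over HTO_M1 (15 up, 1 down; 2.2e-08; 0.0524 estimated) and in HTO_M3 over HTO_M1 (11 up, 2 down; 0.0073; 0.365 estimated), but not in HTO_M3 over HTO_M2 (6 up, 8 down; 0.533). Immediate early genes fell in HTO_M3 (0 up and 11 down against each of the others; 0.00476 and 0.0121; 0.502 and 0.527 estimated), and did not pass in HTO_M2 over HTO_M1 (0 up, 5 down; 0.114). Follicular markers fell in HTO_M3 (1 up and 7 down against HTO_M1, 0.0385; 0 up and 8 down against HTO_M2, 0.00473; 0.496 and 0.463 estimated), with 3 up and 3 down in HTO_M2 over HTO_M1 (0.598). Interferon markers passed in HTO_M2 over HTO_M1 (7 up; 0.0436; 0.691 estimated) and not in the contrasts with HTO_M3 (0.0765 and 0.607), nor did resting markers in any contrast (0.356, 0.124 and 0.268). Lists of other cell types did not pass with camera in HTO_M2 over HTO_M1, HTO_M3 over HTO_M1 or HTO_M3 over HTO_M2 either: B cells (0.275, 0.930, 0.268), conventional CD4 cells (0.945, 0.301, 0.268), gamma-delta T cells (0.893, 0.179, 0.268), myeloid cells (0.113, 0.179, 0.687), NK cells (0.275, 0.928, 0.290) and plasma cells (0.511, 0.930, 0.766). With fry some did: myeloid cells in HTO_M2 and HTO_M3 over HTO_M1 (adjusted p = 0.0024 and 0.00033, up). NK cells did in all 3 contrasts (0.010, up, 0.0012, up, and 0.00052, down). B cells did in HTO_M2 over HTO_M1 (0.014, up) and HTO_M3 over HTO_M2 (0.0021, down), and plasma cells in the latter (0.028, up). Conventional CD4 cells did in HTO_M3 over HTO_M1 and HTO_M2 (0.0050 and 0.0043, down). These lists are short, and single members changed: Tcrg-C1 and Tcrg-C2, 2 of 3 gamma-delta markers, rose in HTO_M3 over HTO_M1 (3.92 and 3.01) and over HTO_M2 (4.24 and 3.23), while Trdc was not called (fry adjusted p for the list 4.2e-05 and 6.4e-05). The myeloid markers Itgam and Cst3 rose over HTO_M1 in HTO_M2 (1.81 and 0.21) and in HTO_M3 (2.08 and 0.26). Of 6 B cell markers, 2 rose and 2 fell in HTO_M3 over HTO_M1 and 4 fell over HTO_M2. These members were chosen after their values were seen. Adjusted over the list alone, effector markers had 16 up and 2 down in HTO_M2 over HTO_M1 and 12 up and 2 down in HTO_M3 over HTO_M1, interferon markers had 3 up and 0 down in HTO_M3 over HTO_M2, and the other counts were the same. Among these lists, the test and the median or mean differed in sign for conventional CD4, follicular and resting markers in HTO_M2 over HTO_M1, for NK and plasma cells in HTO_M3 over HTO_M1, and for plasma cells in HTO_M3 over HTO_M2.

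Within effector-like cells alone, Il2ra rose by 1.75 on the log2 scale in HTO_M3 over HTO_M1 (SE 0.08, adjusted p = 4.3e-13, edgeR), from 168 ± 8.07 to 566 ± 68.9 CPM. Within resting-like cells Il2ra rose by 0.24 (SE 0.08, adjusted p = 0.026, edgeR, 3 of 4 pools), and within follicular-like cells by 0.57 (SE 0.07). Il2rb rose by 1.51 (SE 0.07), 0.31 (SE 0.07) and 0.54 (SE 0.06) in the same classes. Foxp3 was not called in the 3 classes in any of the 3 contrasts. Ctla4 rose in resting-like cells (0.36, SE 0.08, adjusted p = 0.0018, edgeR), and was not called in effector-like (0.18, adjusted p = 0.063) or follicular-like cells (0.08). The resting-like class held 8775 HTO_M1 and 976 HTO_M3 cells. Cluster 3, whose best list was that of resting markers, held 4509 HTO_M3 cells and is in none of these classes. Changes within resting-like cells may therefore depend on how cells were split between these clusters.

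Il10 fell within effector-like cells of HTO_M3 against HTO_M1 by 1.67 (SE 0.49, adjusted p = 0.012, edgeR, 3 of 4 pools) on 43 and 29 UMIs, but without pool 4 it was not called (negative 0.91). It was not called within follicular-like cells (negative 0.42, SE 0.42; 0.16 without pool 4). In HTO_M2 over HTO_M1, Il2rb rose within effector-like cells (0.47, SE 0.07) and fell within resting-like cells (negative 0.33, SE 0.06), while Il2ra fell within resting-like cells (negative 0.21, adjusted p = 0.022, edgeR) and was not called within effector-like cells (0.20, adjusted p = 0.17). In HTO_M3 over HTO_M2, Il2ra rose within effector-like, resting-like and follicular-like cells by 1.55, 0.45 and 0.66, and Il2rb by 1.03, 0.64 and 0.60. Leaving out pools 1 or 2 ended the call of Il2ra within resting-like cells of HTO_M3 over HTO_M1 (0.22 and 0.13), leaving out pools 1 or 4 that of HTO_M2 over HTO_M1 (negative 0.21 and negative 0.19), and leaving out pool 3 those of Ctla4 in resting-like cells of HTO_M2 and HTO_M3 over HTO_M1 (0.13 and 0.21). In resting-like cells of HTO_M2 over HTO_M1, DESeq2 called neither Il2ra (negative 0.21) nor Ctla4 (0.20). Without the pool block neither was called there (negative 0.21 and 0.19), nor in HTO_M3 over HTO_M1 (0.24 and 0.35).

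Within effector-like cells 952, 3189 and 3475 of 10510 genes changed in HTO_M2 over HTO_M1, HTO_M3 over HTO_M1 and HTO_M3 over HTO_M2 (edgeR). Within resting-like cells 1720, 2014 and 604 of 10411 changed, and within follicular-like cells 1118, 2708 and 1133 of 9964. The direction of these counts depends on the scaling. With library size only in place of TMM, the share of called genes that were higher went from 59.0% to 42%, 54.5% to 36.0% and 54.7% to 40.8% within effector-like cells, from 64.9% to 51.0% within resting-like cells of HTO_M3 over HTO_M2, and from 65.7% to 33.3% and 58.9% to 38.3% within follicular-like cells of HTO_M2 and of HTO_M3 over HTO_M1. The median of all genes moved to negative 0.15 within effector-like and negative 0.12 within follicular-like cells of HTO_M3 over HTO_M1. Leaving out pools moved several of these counts by more than 1.5 times. Within effector-like cells the count for HTO_M2 over HTO_M1 was 504 without pool 4. Within resting-like cells it was 1118 without pool 3 and 1335 without pool 4 for HTO_M3 over HTO_M1, and 393 and 253 for HTO_M3 over HTO_M2. Within follicular-like cells it was 684, 726 and 624 without pools 1, 2 and 4 for HTO_M2 over HTO_M1, 1742 without pool 4 for HTO_M3 over HTO_M1, and 748, 751 and 546 without pools 1, 3 and 4 for HTO_M3 over HTO_M2.

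**Figure D2:**
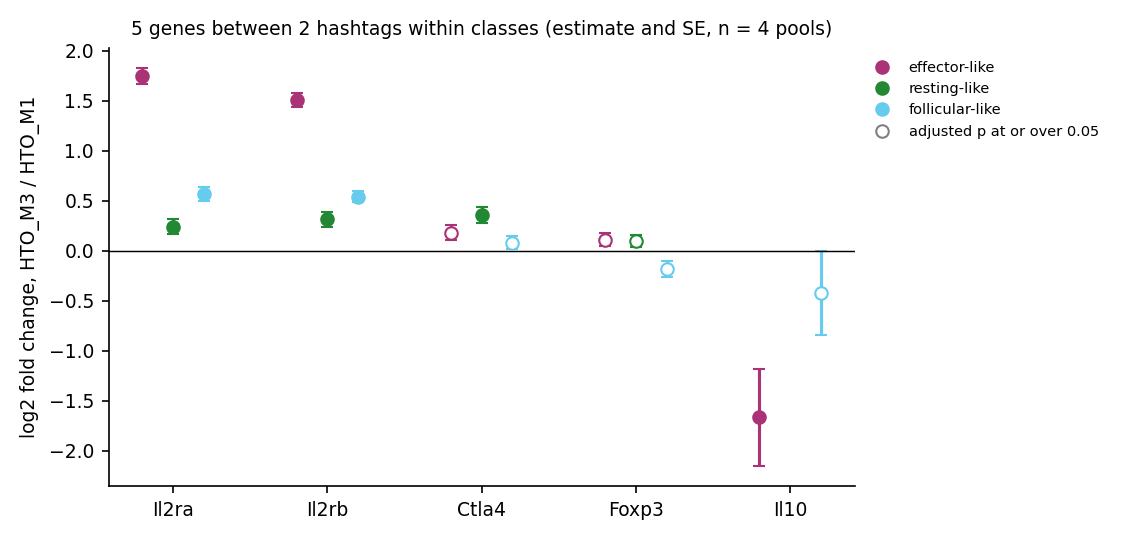
Log2 fold change of 5 genes (Il2ra, Il2rb, Ctla4, Foxp3 and Il10) in HTO_M3 over HTO_M1, fitted within effector-like, resting-like and follicular-like cells. Points are estimates from 4 pools, bars are standard errors of the edgeR fit, and open points did not pass an adjusted p of 0.05. Il2ra stands at 1.75 in effector-like and 0.24 in resting-like cells, and Il10 was too low in resting-like cells to be tested.

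CD25, the protein of Il2ra, averaged 161 ± 28.8 antibody UMIs per cell in HTO_M3, against 35.8 ± 4.92 in HTO_M1 and 31.9 ± 2.25 in HTO_M2, 4.46-fold over HTO_M1 (log2 ratio of 2.16, SD 0.18 over pools). GITR, the costimulatory receptor encoded by Tnfrsf18, averaged 27.8 ± 3.67, 38.7 ± 4.85 and 82.1 ± 6.56 in HTO_M1, HTO_M2 and HTO_M3, 2.97-fold higher in HTO_M3 than in HTO_M1. ICOS averaged 3.92 ± 0.388, 6.93 ± 1.02 and 8.74 ± 0.991. CD44, an adhesion receptor of activated cells, averaged 240.0 ± 35.7, 217.9 ± 34.2 and 245 ± 35.3. PD-1, the inhibitory receptor encoded by Pdcd1, averaged 14.3 ± 2.51, 9.88 ± 1.81 and 8.32 ± 0.803.

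The exact permutation p was 0.0286 for CD25 and GITR in HTO_M3 against each of the others, for ICOS and PD-1 in HTO_M3 against HTO_M1, and for ICOS and GITR in HTO_M2 against HTO_M1, each in 4 of 4 pools, and the adjusted p over 18 tests was 0.0514, so none passed 0.05. That exact p is the smallest that 4 against 4 mice allow. Its adjusted value rests on how many of the 18 tests reached it, not on the size of a difference. The other 7 contrasts of these 5 proteins gave exact p from 0.0571 to 0.857. By median UMIs per cell PD-1 was highest in HTO_M3 (5, against 4.25 in HTO_M1 and 4 in HTO_M2), the hashtag with the lowest mean. The difference of CD44 between HTO_M3 and HTO_M1, 0.03 on the log2 scale (exact p = 0.857), reversed without pool 3 (exact p = 0.9).

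**Figure D3:**
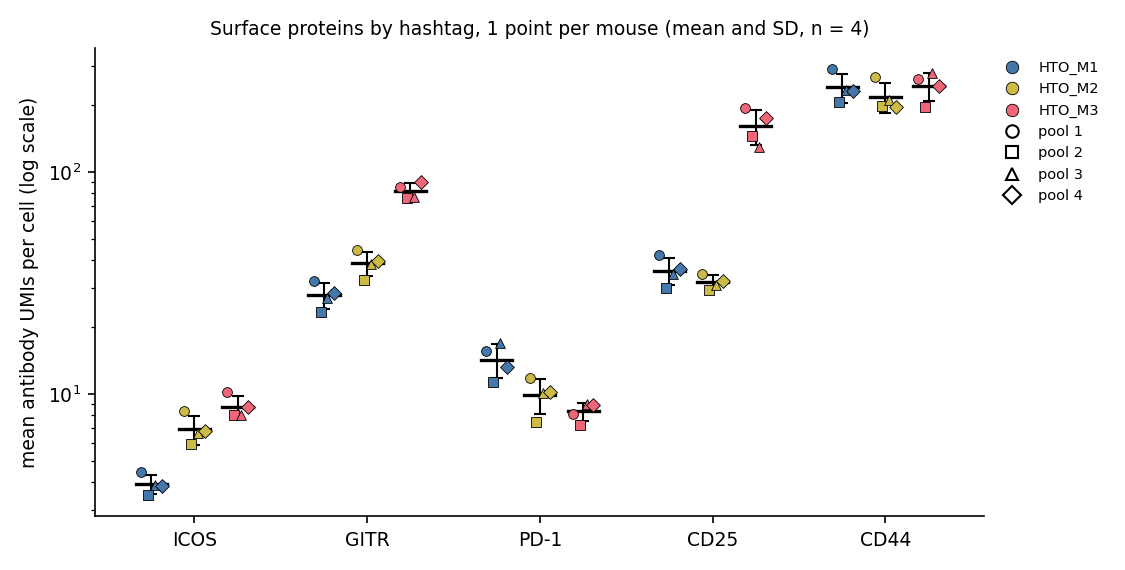
Mean antibody UMIs per cell (log scale) of 5 surface proteins by hashtag; each point is a mouse, its shape the pool, and bars give the mean and SD over 4 mice. CD25 averages 161 UMIs in HTO_M3 and 35.8 in HTO_M1, while CD44 averages 245 and 240.0.

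Between effector-like and resting-like cells, only genes that were left out of the clustering are results. Il10 had 178 UMIs in effector-like cells and 1 in resting-like cells, a ratio of 223 per total UMIs (95% counting interval 39.5 to 8864). Tigit, an inhibitory receptor, rose by 6.80 (SE 0.08, adjusted p = 6.3e-23, edgeR), and Ccr2 by 7.16 (SE 0.10), Gzmb by 5.27 (SE 0.12), Cxcr3 by 4.80 (SE 0.07) and Ccr4 by 4.68 (SE 0.09). Havcr2, the inhibitory receptor TIM-3, had 102 UMIs in effector-like and 0 in resting-like cells, at least 42.6-fold higher against a floor of 3 counts over the group. Ctla4 rose by 0.96 (SE 0.03), and Myc fell by 1.65 (SE 0.04).

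Of 138 tested genes of the 7 outcome lists, 122 changed between effector-like and resting-like cells (edgeR), 92 up and 30 down. Over all genes, those used for the clustering included, 7993 of 11484 were called, so most of any list would be. Tbx21, a transcription factor of type 1 helper T cells, rose by 4.06, with Cd80 (2.78), Socs2 (2.17), Tnfsf14 (1.81), Cdk6 (1.18), Tpi1 (1.09), Hk2 (1.02), Mvd (0.88) and Stard4 (0.77). Falls were of Eomes (3.41), the survival gene Bcl2 (1.54), Prf1 (1.48), Gpr83 (1.30), Foxp1 (1.06), Tnfsf8 (0.97), Cd160 (0.79) and Cxcr4 (0.46). Il2rb rose by 0.40 (SE 0.03), Il2ra by 0.32 (SE 0.03) and Foxp3 by 0.09 (SE 0.03, adjusted p = 0.0071, edgeR), but effector-like cells come mostly from HTO_M2 and resting-like cells from HTO_M1. With the mouse as block, 102 outcome genes changed, and Il2ra (negative 0.08), Il2rb (0.06), Foxp3 (0.06), Cxcr4 (negative 0.15), Insig1 (negative 0.10) and Slc2a3 (0.06) were not called. At a resolution of 1.0 Cd160 (negative 0.08) and Foxp3 (0.03) were not called, and with outcome genes kept in the clustering Il2rb (0.01) and Foxp3 (0.05) were not. With outcome genes kept in the clustering Il2ra fell by 0.25. DESeq2 did not call Insig1 (negative 0.19) or Slc2a3 (0.17). Without the pool block Foxp3 (0.09), Eno1 (0.15) and Slc2a3 (0.15), with library size only Insig1 (negative 0.07) and with the strict filter Slc2a3 (0.10) were not called. Without pool 2 Eno1 (0.10), without pool 1 Insig1 (negative 0.14) and without pool 4 Slc2a3 (0.11) were not called.

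Suppression genes had 15 up (Tigit, Gzmb), 1 down (Prf1) and 1 not called in effector-like cells (camera adjusted p = 1.1e-05; adjusted p = 0.0795 with an estimated correlation). Homing genes had 15 up (Ccr2, Cxcr3) and 4 down (Gpr83, Cxcr4) (0.000235; 0.0795 estimated), and glycolysis genes 13 up (Tpi1, Hk2) and 2 not called (0.000243; 0.375 estimated). Transcription factors had 17 up (Tbx21 among them), 7 down (Eomes, Foxp1) and 2 not called (0.0271, up; 0.375 estimated), and cholesterol synthesis 11 up (Mvd, Stard4), 3 down (Insig1 among them) and 5 not called (0.0470, up; 0.397 estimated). Costimulation (11 up, 6 down, 2 not called; 0.109) and IL-2 and STAT5 response (10 up, 9 down, 4 not called; 0.931) did not pass. When adjusted over the list alone, the counts were the same. Genes used for the clustering, such as Ly6c1, Atp1b1 and Ms4a4c (higher in resting-like cells) and Myo1f, Gbp2b and Ifitm1 (higher in effector-like cells), define the classes and are not results. With library size only, the median of all genes was 0.11 (negative 0.03 with TMM) and 65.1% of called genes were higher, against 48.8% with TMM.

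In cycling-like cells, set against all other cells, Gzma rose by 2.29 (SE 0.05, adjusted p = 1.3e-09, edgeR), Gzmb by 1.68 (SE 0.07), the glycolytic enzymes Tpi1 by 1.6 (SE 0.03) and Pgam1 by 1.19 (SE 0.04), and the sterol enzyme Idi1 by 1.09 (SE 0.04). Ccr6 fell by 3.12 (SE 0.15), Cd83 by 2.5 (SE 0.08) and Il10 by 1.54 (SE 0.36, adjusted p = 0.0035, edgeR). Cycling-like cells had a median of 14546 UMIs, and the other classes and clusters had medians of 2215 to 8093. A fall relative to total UMIs, of Il10 or of any other gene in this comparison, therefore need not be a fall per cell. Changes per cell were not tested here. Of 5291 cycling-like cells, 5045 were HTO_M3 cells. Within HTO_M3 cells alone Il10 was not called (negative 0.55). Socs2 and Il2rb, higher by 0.78 and 0.48 over all hashtags, stood there at negative 0.18, a called fall, and negative 0.07, not called.

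Of 140 tested outcome genes, 121 changed in cycling-like cells (51 up, 70 down, edgeR), and 98 changed in HTO_M3 cells alone (25 up, 73 down). Over all hashtags 9428 of all 12501 genes were called, those used for the clustering included. Il2ra rose by 0.72 (SE 0.03) over all hashtags and by 0.10, not called, in HTO_M3 cells alone. Relative to total UMIs, Foxp3 fell by 0.28 (SE 0.04), which need not be a fall per cell. Ctla4 was not called (0.06, SE 0.04, and negative 0.07 with library size only). Myb (1.37), Stard4 (1.06), Ccnd3 (0.88), Id3 (0.50) and Tnfrsf18 (0.25; 0.04, not called, in HTO_M3 cells alone) rose, and Eomes (2.33), Cxcr6 and Itgb8 (both 1.95), Tnfsf8 (1.27), Slc2a3 (1.10), Stat5b (0.83), Mcl1 (0.59), Aldoa (0.39) and Srebf2 (0.20) fell. Cholesterol synthesis had 15 up (Idi1, Stard4), 1 down (Srebf2) and 3 not called (camera adjusted p = 0.00550; adjusted p = 0.453 with an estimated correlation), and glycolysis 10 up (Tpi1, Pgam1), 3 down (Slc2a3, Aldoa) and 2 not called (0.0359; 0.453 estimated). Costimulation had 2 up, 15 down (Cd83, Tnfsf8) and 2 not called (0.00550, down), homing 3 up, 13 down (Ccr6, Cxcr6) and 4 not called (0.0318, down), and transcription factors 5 up (Myb, Id3), 18 down (Eomes among them) and 4 not called (0.0359, down), each with 0.453 estimated. IL-2 and STAT5 response (12 up, 9 down, 2 not called; 0.436) and suppression (4 up, 11 down, 2 not called; 0.155) did not pass. With p values adjusted over the list alone, cholesterol synthesis had 16 up and homing 4 up, and the other 5 lists were unchanged. Without pools 2, 3 and 4 neither Cd81 (0.10, 0.07 and 0.13) nor Insig1 (0.14, 0.13 and 0.12) was called. The number of lists past 0.05 fell from 5 of 7 to 3 without pool 2. Genes used for the clustering, such as Pimreg, Pbk and Mxd3, define the class. With library size only, the median of all genes was negative 0.17 (negative 0.04 with TMM) and 38.6% of called genes were higher, against 48.4% with TMM.

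Il10 transcripts were rare. At least 1 UMI was seen in 119 of 7996 effector-like cells (1.49%, exact interval 1.23% to 1.78%), 138 of 6718 follicular-like cells (2.05%), 27 of 5291 cycling-like cells (0.510%) and 1 of 15277 resting-like cells (0.00655%), the background here, at median depths of 6056.5, 4325, 14546 and 4354 UMIs. By hashtag, 148, 209 and 128 Il10 UMIs came from 91 HTO_M1, 126 HTO_M2 and 76 HTO_M3 cells.

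Effector-like cells with an Il10 UMI were compared with depth-matched effector-like cells without one. Lag3, an inhibitory receptor, rose by 3.95 (SE 0.25, adjusted p = 1.8e-10, edgeR), from 23.9 ± 18.9 to 438 ± 82.1 CPM. Cxcr6, a receptor of tissue-resident cells, had 107 UMIs in positive and 3 in negative cells, a ratio of 35 per total UMIs (95% counting interval 11.7 to 172). The ubiquitin ligase adaptor Asb2 rose by 2.78 (SE 0.41; 0.62, not called, without cells near hashtag doublets), the chemokine Ccl5 by 2.53 (SE 0.37), the secreted suppressor Fgl2 by 2.19 (SE 0.39) and Ctla4 by 1.07 (SE 0.12). Asb2 and Ccl5 are also among the top genes of the follicular-like cluster. Whether positive cells near that cluster give their rise was not tested. The adaptor Pdlim1 fell by 2.65 (SE 0.26), and Trat1, a T cell receptor adaptor, by 2.60 (SE 0.35).

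The comparison held 119 cells on each side, 18 to 42 per pool, and 255 of 3467 genes changed (138 up, 117 down, edgeR), of them 18 of 83 outcome genes (16 up, 2 down). Podnl1 (2.55), Adam8 (2.25), the transcription factors Id2 (1.65) and Ikzf3 (0.98), Tnfrsf1b (1.38), Ccr2 (1.09), the nucleotidase Nt5e (0.85), Cd27 (0.66), Tnfrsf18 (0.57) and Pkm (0.33) rose. Nsg2 (1.83), Aff3 (1.64), Id3 (1.52), Rflnb (1.41), Evl (1.38), Adam17 (1.33) and the integrin Itgb1 (1.05) fell. Il2ra (0.09; negative 0.25 without pool 4), Foxp3 (0.12) and Il2rb (0.23) were not called. Suppression genes had 7 up (Lag3, Fgl2) and 3 not called (camera adjusted p = 8.0e-09; adjusted p = 0.0903 with an estimated correlation), costimulation 3 up (Tnfrsf1b, Cd27) and 6 not called (0.0104; 0.317 estimated), homing 3 up (Cxcr6, Ccr2), 1 down (Itgb1) and 10 not called (0.0257; 0.227 estimated), and transcription factors 2 up (Id2, Ikzf3), 1 down (Id3) and 13 not called (0.0257; 0.227 estimated). Glycolysis (1 up, 10 not called; 0.126), cholesterol synthesis (6 not called; 0.248) and IL-2 and STAT5 response (17 not called; 0.790, up with a median just under 0) did not pass. Adjusted over the list alone, costimulation had 4 up, glycolysis 2 up and homing 3 up and 2 down, and the other 4 lists kept their counts. The number of lists past 0.05 fell from 4 of 7 to 2 without pool 1 and to 2 without pool 2.

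Effector markers rose with Il10 (12 up, 1 down; camera adjusted p = 1.4e-09; 0.221 estimated), and resting markers fell (0 up, 5 down; 1.1e-05; 0.221 estimated). Immediate early (3 up; 0.186), follicular (2 up, 1 down; 0.682), interferon (10 not called; 0.707), cycling (1 up, 1 down; 0.707) and B cell markers (2 not called; 0.929) did not pass. The cycling list tested down with a mean just above 0. When adjusted over the list alone, effector markers had 13 up and 1 down, resting markers 0 up and 6 down and immediate early genes 4 up. The count of 255 genes fell to 133 without pool 1 and 158 without pool 4. The balance of rises and falls depends on the choices: 117 up and 62 down in a second random draw (179 genes), 88 and 45 when matched on hashtag as well, 76 and 30 without the pool block, 71 and 39 with the strict filter and 68 and 20 at a resolution of 1.0, but 92 and 110 with outcome genes kept in the clustering and 37 and 42 with DESeq2. Without pool 1 Ccr2 (0.82), Pkm (0.37), Nsg2 (negative 1.39), Rflnb (negative 1.51) and Adam17 (negative 1.28) were not called, without pool 3 Adam17 (negative 1.15), without pool 4 Tnfrsf18 (0.50), Pkm (0.20) and Adam17 (negative 1.53), and without any 1 of the 4 pools Nt5e (0.76 to 0.94). Matched on hashtag as well, Podnl1 (0.77), Adam8 (1.26), Ikzf3 (0.61), Ccr2 (0.97), Nt5e (0.33), Pkm (0.35), Nsg2 (negative 1.62) and Rflnb (negative 1.10) were not called. In a second random draw Id2 (0.87) and Nt5e (0.78) were not called. With at least 2 Il10 UMIs these were Ccr2 (0.20), Ikzf3 (0.84), Cd27 (0.55), Pkm (0.42) and Evl (negative 1.26), and with the strict filter Podnl1 (1.00), Tnfrsf18 (0.21) and Pkm (0.28). At a resolution of 1.0 they were Tnfrsf18 (0.34), Nt5e (0.81) and Pkm (0.27), with outcome genes kept in the clustering Cd27 (0.26) and Pkm (0.35), and without cells near hashtag doublets Tnfrsf18 (0.38) and Pkm (0.31) beside Asb2. DESeq2 did not call Tnfrsf18 (0.57), Ccr2 (1.04) or Pkm (0.31). Without the pool block Nt5e (0.85) and Pkm (0.32), without the count filter Pkm (0.32) and without depth matching Adam17 (negative 0.74) were not called.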

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

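The tests of RNA content and of class mix for Il10, the comparison of CD25 with CD44 and the tests of a difference between effector-like and resting-like cells were chosen after the results were seen, whereas the splits of the libraries and the test of CD25 outside cycling-like cells were set before theirs. In 57 groups of 4 mice, the mouse farthest from the others was set against the range of its group, and 5 groups had an outlying mouse. Chance gives about 1 in 20. In HTO_M1 and HTO_M2 the share of cluster 7 was highest in pool 2, at 3.38% and 4.30%, and the gap to the nearest mouse made up 0.848 and 0.862 of the range. In HTO_M1 pool 4 had 1.21% cycling-like cells (0.886 of the range) and an Il10 CPM of 4.82 (0.894), while the 4 mice had medians of 0.253% and 1.87. In HTO_M3 the median number of genes per cell was 2476 in pool 3 (0.918), against a median of 2739 over the 4 mice.

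The effect of the hashtag on the IL-2 receptor genes differed between effector-like and resting-like cells, as an interaction term in edgeR. The resting-like side leaves out unnamed cluster 3, whose best list was that of resting markers. CD25 averaged 107 ± 17.6 antibody UMIs in its 4509 HTO_M3 cells and 50.8 ± 11.1 in the 976 resting-like HTO_M3 cells. The size of the difference may therefore depend on which cells are counted as resting-like. Il2ra rose more in effector-like cells by 1.47 on the log2 scale in HTO_M3 over HTO_M1 (adjusted p = 3.7e-18) and by 1.07 in HTO_M3 over HTO_M2 (1.0e-15), and its change was more positive by 0.40 in HTO_M2 over HTO_M1 (0.0011). For Il2rb the differences were 1.16 (4.4e-16), 0.35 (0.00012) and 0.81 (3.9e-11). Of 10158 genes, 1391, 969 and 290 had such a difference in HTO_M3 over HTO_M1, HTO_M3 over HTO_M2 and HTO_M2 over HTO_M1. Foxp3 and Ctla4 had none that passed.

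CD25 protein was 4.46-fold higher in HTO_M3 than in HTO_M1 (n = 4). A general rise of antibody UMIs on HTO_M3 cells was set against CD44, whose mean log2 ratio of HTO_M3 to HTO_M1 was 0.03 (0.0270, SD 0.178) where that of CD25 was 2.16 (SD 0.175). This argues against a rise of all antibodies by as much as that of CD25. The log2 change of Cd44 mRNA was -0.46 (edgeR), so a flat CD44 cannot exclude a smaller rise of all antibodies. Other antibodies moved too, among them ICOS by 1.16 and GITR by 1.57 up and PD-1 by -0.76, so a rise shared by several antibodies may be part of that of CD25 and stays open. A rise in cycling-like cells alone is argued against as well, since outside that class the mean log2 ratio of CD25 was 1.71 (SD 0.151, 3.27-fold, n = 4). Unequal treatments of the mice may underlie the difference, and this stays untested, as no label ties a hashtag to a treatment.

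Il10 fell in CPM between HTO_M1 and HTO_M3, from 2.52 ± 1.54 to 0.809 ± 0.370 (SD, n = 4, exact permutation p = 0.0286). A larger RNA content of HTO_M3 cells could lower CPM without fewer Il10 transcripts per cell. Per 1000 cells there were 10.8 ± 7.16 and 8.58 ± 3.82 Il10 UMIs, lower in 2 of 4 pools (exact permutation p = 0.714), so this explanation cannot be told apart from a fall per cell at 4 mice and these counts. A changed mix of classes would leave Il10 equal within effector-like and follicular-like cells. The lower of the 2 ratios of log2 change to SE was -3.42 with all pools, but -1.30 without pool 4, the pool with the outlying HTO_M1 value, so 1 pool decides this and the class mix stays open too.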

How the results depend on the processing

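The library-size scaling, the mouse block, HTO_M3 cells alone, hashtag matching, the clustering without hashtag genes, the removal of cells near doublets or of the low-UMI cluster, the second draw, the medians of antibodies and all alternatives within classes, for proteins and Mki67, and for class shares between hashtags other than sign flips and the ratio rule for hashtag calls were chosen after seeing the data; the others were planned. Keeping the cells that Scrublet calls was not run, as it called 0 cells. Unless a cause is given below, the cause was not tested.

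The counts of genes between hashtags stayed within 1.5 times of those reported under all 13 alternatives (3454 to 4939 for HTO_M2 over HTO_M1, 7755 to 8853 for HTO_M3 over HTO_M1 and 7291 to 8451 for HTO_M3 over HTO_M2). So did the outcome genes of effector-like cells (102 to 125) and cycling-like cells (98 to 124). The Il10 comparison varied most. Its 255 genes became 79 with DESeq2, 106 without the pool block, 110 with the strict cell filter, 88 at a resolution of 1.0, 95 with at least 2 Il10 UMIs, 133 when matched on hashtag, 133 to 226 on leaving out a pool and 678 without depth matching, where all other effector-like cells are used.

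With DESeq2 the counts within classes fell to 2306 for HTO_M3 over HTO_M2 in effector-like cells, 946 for HTO_M2 over HTO_M1 in resting-like cells, and 563, 1414 and 546 in follicular-like cells. Leaving out a pool, which takes 2 of 8 libraries from each contrast, gave 504 to 731 for HTO_M2 over HTO_M1 in effector-like cells, 1118 to 1908 and 253 to 494 for HTO_M3 over HTO_M1 and over HTO_M2 in resting-like cells, and 624 to 747, 1742 to 2252 and 546 to 922 in follicular-like cells.

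Of the outcome lists past 0.05 with camera (5, 3 and 6 of 7 between hashtags, 5 for effector-like cells, 5 for cycling-like cells and 4 for Il10), 0 passed with an estimated correlation in each comparison. Unadjusted, suppression (0.0140) and homing (0.0227) in effector-like cells and suppression for Il10 (0.0129) were under 0.05. With fry 6 lists passed for HTO_M3 over HTO_M1 and 2 for Il10. Leaving out a pool gave 3 to 5 lists for HTO_M2 over HTO_M1, 3 to 5 for cycling-like cells and 2 to 3 for Il10.

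Class shares between hashtags that passed had a p of 0.13 with within-pool sign flips and 0.1 on leaving out any pool, as did Mki67 shares with 0.1; these are the smallest values those designs allow and say nothing of stability. Resting-like cells of HTO_M2 against HTO_M1 had 0.714 at a resolution of 1.0, effector-like cells of HTO_M3 against HTO_M1 0.0571 with outcome genes in the clustering, and cycling-like cells of HTO_M2 against HTO_M1 passed with the strict filter (0.0286). Interferon-like cells, called in no contrast, changed direction. Leaving out a pool gave 0.3 to 1 for HTO_M2 and for HTO_M3 against HTO_M1, and 0.3 to 0.8 for HTO_M3 against HTO_M2, which also reversed at a resolution of 1.0 (0.4), with outcome genes (0.629), with the strict filter (0.629), without hashtag genes (0.114) and without cells near doublets (1).

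Shares by pool moved by more than 1 SD at a resolution of 1.0 for resting-like (8.15%), effector-like (12.7%), follicular-like (11.5%) and interferon-like cells (3.33%), with outcome genes for effector-like cells (15.6%), and without hashtag genes for cycling-like (9.33%) and interferon-like cells (2.94%). By median UMIs PD-1 reversed for HTO_M3 against HTO_M1 and HTO_M2 (0.143 each) and CD44 for HTO_M2 against HTO_M1 (0.6). CD44 of HTO_M3 against HTO_M1 had 0.6 to 1 on leaving out a pool.

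Of values of single named genes under an alternative, 3603 were unchanged in direction and call, 133 lost the call, 18 gained it and 45 reversed. In HTO_M3 over HTO_M1, Foxp3 reversed with DESeq2 (0.015), RLE factors (0.0013), no count filter (0.032) and the hashtag rule (0.0036), and had -0.045 to 0.040 on leaving out a pool. In HTO_M3 over HTO_M2, Ctla4 reversed with DESeq2 (0.012), RLE factors (0.0014) and no count filter (0.028), with -0.093 to 0.023 on leaving out a pool, and Foxp3 with library size only (-0.057). In HTO_M2 over HTO_M1, Il10 had -0.12 to 0.41 on leaving out a pool. In effector-like over resting-like cells, Il2ra and Eno1 reversed with outcome genes kept (-0.25 and -0.14) and the mouse block (-0.085 and -0.017), and Insig1 at a resolution of 1.0 (0.40). In cycling-like cells, Ctla4 and Cd81 reversed with library size only (-0.072 and -0.014), Cxcr4 and Cd81 with thinned cells (-0.0065 and -0.14), and Ctla4, Socs2 and Il2rb in HTO_M3 cells alone (-0.068, -0.18 and -0.069). With Il10, Il2ra reversed with the strict filter (-0.39), at a resolution of 1.0 (-0.12) and without cells near doublets (-0.23), with -0.25 to 0.25 on leaving out a pool, and Foxp3 at a resolution of 1.0 (-0.0022) and with at least 2 Il10 UMIs (-0.46).

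Within effector-like cells, library size only reversed Ctla4 in HTO_M2 over HTO_M1 (-0.032) and Foxp3 in HTO_M3 over HTO_M1 (-0.0030), and no count filter reversed Foxp3 in HTO_M2 over HTO_M1 (0.0082). On leaving out a pool that contrast gave -0.037 to 0.061 for Ctla4 and -0.097 to 0.0093 for Foxp3, and within resting-like cells -0.059 to 0.0021 for Foxp3. Within follicular-like cells, Ctla4 reversed in HTO_M3 over HTO_M1 with library size only (-0.0078). On leaving out a pool Il10 had -0.44 to 0.23 in HTO_M2 over HTO_M1, -1.2 to 0.16 in HTO_M3 over HTO_M1 and -1.16 to 0.094 in HTO_M3 over HTO_M2, where Ctla4 had -0.10 to 0.0032 and Foxp3 -0.094 to 0.058. Depth limits what can be said of Il10, which had 148, 209 and 128 UMIs in HTO_M1, HTO_M2 and HTO_M3.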

Other observations

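The tests on Lag3, Maf and Tigit and the splits of the libraries were set before their results were seen; the values by class were looked at after.

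For each comparison of genes, the 8 libraries were split into 4 and 4 in all 35 ways and fitted without the pool block. In all 15 comparisons 1 of 35 splits, the real one, gave as many genes as the real split. For effector-like against resting-like and for cycling-like against other cells the groups were drawn by clustering on expression, so the real split was bound to give most genes and the count says nothing there. In the other 13 comparisons no other split of the libraries gave as many genes. Between hashtags the real splits gave 4602 genes for HTO_M2 against HTO_M1, 8178 for HTO_M3 against HTO_M1 and 7881 for HTO_M3 against HTO_M2, and the highest of the other splits gave 1, 0 and 0. The classes gave 116 (effector-like) and 112 (cycling-like) outcome genes against 0, and Il10-positive cells 106 genes against 2. Within effector-like cells the values were 920, 2831 and 3299 against 7, 0 and 0, within resting-like cells 1323, 1631 and 430 against 2, 0 and 8, and within follicular-like cells 1012, 2305 and 856 against 1, 0 and 1, in the order HTO_M2 over HTO_M1, HTO_M3 over HTO_M1 and HTO_M3 over HTO_M2. Of the 8 splits that part the libraries of all 4 pools, as the real one does, the other 7 gave 0 genes, except within follicular-like cells of HTO_M3 against HTO_M2, where the highest gave 1. These 8 splits alone are too few for a share under 0.05.

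Lag3, Maf and Tigit, a pattern seen in the data and tested on the same data, were higher in Il10-positive than in Il10-negative effector-like cells, by 3.95 (SE 0.25), 1.57 (SE 0.14) and 1.70 (SE 0.17) on the log2 scale. Over the alternatives the lowest values were 2.79 for Lag3 and 0.95 for Maf with the strict cell filter and 0.76 for Tigit with outcome genes kept in the clustering, and the highest were 4.50, 1.72 and 1.90. Unequal hashtags in the 2 groups could give this, but matched on hashtag as well the smallest ratio of change to SE over the 3 genes was 8.48. Doublets among positive cells could too, but without cells near hashtag doublets the smallest ratio was 6.86. Both values argue against these explanations as the whole cause for these 3 genes alone. The rise of Asb2 by 2.78 became 0.62, not called, without cells near hashtag doublets, and that of Podnl1 by 2.55 became 0.77, not called, when matched on hashtag as well, so for them these explanations stay open. Doublets within a mouse were not tested.

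CD25 antibody UMIs per cell averaged 35.5 ± 5.20, 27.8 ± 3.39 and 50.8 ± 11.1 in resting-like cells of HTO_M1, HTO_M2 and HTO_M3 (SD, n = 4). In effector-like cells they averaged 20.8 ± 1.21, 32.3 ± 1.42 and 162 ± 30.6, and in follicular-like cells 39.8 ± 8.31, 37.2 ± 2.62 and 88.8 ± 15.1. Cd79a, a B cell gene, had a UMI in 0.313% of follicular-like, 0.4% of effector-like, 0.419% of resting-like and 0.473% of cycling-like cells. Lyz2, a myeloid gene, had one in 0.0196% of resting-like and 0.164% of follicular-like cells. Their source was not tested.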
